A study of Mus musculus with 20 samples.

How the data were processed

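RNA was measured in 20 libraries of mouse aortic tissue, 5 for each of WT young, WT aged, KO young and KO aged, per the labels. Per the labels' protocols, each library pooled tissue of 2 female mice and was made with a stranded low-input kit. Per the submitters' processing notes, the tools named were STAR 2.7.11b, featureCounts of Subread 2.0.8, MultiQC 1.25.1 and DESeq2 1.42.1, with the genome build GRCm39. The role and settings of each tool are not given in the sources used here.

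The files used hold 3 tables of comparisons made by the authors, one row per called gene. Per the file headers, the authors deposited a p-value and an adjusted p-value, a log2 fold change with its standard error, and a mean normalized count for each gene. The deposited mean normalized count is a signal pooled over the libraries of a comparison, and the deposited log2 fold change is rounded to 2 decimals. The tests behind the deposited p-values were the authors', whose processing notes name DESeq2. No value per library entered this work, so library depth is unknown, no model was refitted, and depth sets no interval here. Tables were normalized separately, and levels are compared only within a table. The check of direction and the estimate for Slc24a4 are exceptions, since they carry group means from one table to another. Sums and differences of fold changes also join values from tables that were normalized separately.

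Each table was checked for what it holds. The number of tested genes was recovered from the ratio of adjusted to raw p of the first row, giving 14374, 14661 and 14477, and the rank implied for the last row equalled the number of rows, 1728, 1141 and 2083, so that each table holds the called genes down to its last row. The largest adjusted p was 0.0494 in each table. Genes that were tested and not called are not named in these tables and were not used here, so no enrichment against tested genes was computed. The deposited log2 fold changes divided by their SE had a median of 0.858, 0.841 and 0.865 of the z implied by the p-value, which shows shrinkage; 198, 137 and 190 genes fell under 0.7 of it.

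The direction of each deposited fold change is not stated in the headers and was taken from the values. For each gene the means of both groups follow from the mean and the fold change, and the group shared by a pair of tables must give equal means. With a positive value read as higher in the aged group, the shared WT aged means had a median absolute deviation of 0.0286 on the log2 scale against at least 0.185 for the other pairings. The shared KO young means gave 0.0353 against at least 0.115. The KO young against WT aged table was deposited with WT aged as the positive side, and its sign was turned for the text.

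Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The groups, tests, alternatives and 42 gene lists, with 1226 genes, were fixed before the data were examined, except those named below as chosen or added later. For each list with at least 5 called genes in a comparison, a two-sided Fisher's exact test compared higher and lower genes of the list with those of all other called genes, and the 55 tests were adjusted together by Benjamini-Hochberg; 13 passed 0.05 and 25 had an unadjusted p under 0.05. The test asks about direction among called genes, treats genes as independent, and an estimated correlation between genes could not be used. Adjusted over the list alone, with genes not called set to a p of 1, fewer genes passed than were called over all genes in 13 of 126 pairs of list and comparison. Of the lists, 6 had no called gene.

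Overlaps were counted per direction, with the smaller number of tested genes standing in for the number tested in both. For pairs of tables that share a group, 2000000 pairs of z values with a correlation of 0.5 were drawn and passed through the p of the last called gene of each table. Differences of ageing effects were divided by the root of the summed squared SEs, compared with a normal distribution and adjusted by Benjamini-Hochberg over the 438 genes in both tables. These scripts were tested on simulated counts of 5000 genes with known changes: 199 of 199 genes with opposite effects and 3 of 199 genes with equal effects were called different between the ageing comparisons, and the shared groups were recovered. The simulated fold changes were not shrunken and were larger than most deposited ones. These counts therefore check the computation and give no error rate or power for the deposited values.

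The genes named in the text follow a rule fixed before the data were examined. It takes Slc24a4, the 10 largest increases and decreases per comparison among named genes with a mean normalized count of at least 50, and up to 4 genes with the smallest adjusted p from each list with at least 3 called genes. It also takes 6 genes for each shared direction and for each side of the genotype difference, and the sex-linked controls. Where several genes share a list, those printed are examples of that rule. Some genes that the rule takes are not reported here. Genes were matched by symbol. The gene annotation at hand is of GRCm38 and not of the authors' GRCm39, so no coordinates are printed and it served only for names and gene order. Alternatives were an adjusted p under 0.01, an absolute log2 fold change of at least 1, a mean normalized count of at least 50, and named symbols only.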

Results

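The data set measured gene expression by RNA sequencing in aortic tissue of female mice, in 4 groups defined by age and by genotype at Slc24a4, a gene that encodes a potassium-dependent sodium/calcium exchanger. Young mice were 12 to 15 weeks old and aged mice 72 to 78 weeks old. Each group held 5 libraries and each library pooled the aortas of 2 mice, so that 20 libraries entered the study. Wild-type animals are called WT, and animals that the submitters' labels give as deficient in Slc24a4 are called KO. The values used here are 3 tables of genes that the authors called changed, comparing WT aged with WT young, KO young with WT aged, and KO aged with KO young. Values per library were not analysed here, so the depth of each library is unknown and no error per library is given. Log2 fold changes are those of the authors' deposited tables, in most cases with the standard error (SE) given there, and every gene listed has an adjusted p under 0.05 there. Those fold changes are shrunken towards 0, and the p-values rest on the spread between 5 pools per group.

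Slc24a4 itself fell with age in WT aorta. In the authors' deposited table its log2 fold change was −2.00 (SE 0.46, adjusted p = 1.4e-05), and its mean normalized count of 325 in that authors' deposited table corresponds to about 520 in WT young and 130 in WT aged. It was the gene with the fifth largest decrease among the genes named by the rule on size. The gene was listed in 1 of the 3 tables and in neither table with a KO group, although each table holds every called gene. With the 130 in WT aged carried over from WT ageing and none in KO young, its mean in KO young against WT aged would be about 64.9. This is rough, since the comparisons were normalized separately and the 130 rests on a shrunken fold change. KO young against WT aged called 63 genes with means from 64.9 to 130, with a median absolute log2 fold change of 0.75. A loss of Slc24a4 RNA in KO young aorta is not seen in these tables. The 63 are called genes only, so they cannot show that a loss at such a mean would have been called. Whether the label means absence of its RNA is therefore not settled here. Loss in both KO groups would also leave the gene unlisted in KO ageing. A level in KO young like the 520 of WT young would stand as far from WT aged as the change called in WT ageing, and is not seen either. A level in KO young near that of WT aged, or a gene left without an adjusted p, would go unlisted. The submitters' titles name knockdown and KO together. KO stands throughout for the libraries labelled so, and every direction drawn from them rests on that label. None of the sex-linked control genes Xist, Ddx3y, Kdm5d, Uty and Eif2s3y was listed in any table.

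The first comparison asked which genes changed with age in WT aorta. Aged WT aorta had more RNA of every called complement gene. It had less RNA of most called TGF-beta and BMP signalling genes and of every called immediate early gene. The authors' deposited table gave the largest increases for Cntn1, a neural cell adhesion molecule (log2 fold change 3.52, SE 0.25), and the collagen gene Col6a5 (3.17, SE 0.92). Next in the authors' deposited table were Igfbp2, an insulin-like growth factor binding protein (3.06, SE 0.51), and Spp1, which encodes osteopontin (3.00, SE 0.32). Sphkap at 2.60, Nfasc at 2.55, Nkain2 at 2.40, Tnni3k at 2.21, Oxtr at 2.18 and Ano4 at 2.14 came after them in the authors' deposited table. Among the largest decreases in the authors' deposited table were those of Dner (−2.41, SE 0.45), the stress-induced transcription factor gene Atf3 (−2.20, SE 0.76) and Tmem26 (−2.06, SE 0.29). Below these stood Slc24a4 and, in the authors' deposited table, the cardiac actin gene Actc1 (−1.99, SE 0.40). Galnt6 (−1.91), Rimklb (−1.86), Kcnc4 (−1.69) and Aplp1 (−1.68) followed in the authors' deposited table. In all, 1728 of 14374 tested genes were called at an adjusted p under 0.05, of which 756 were higher and 972 lower in aged WT aorta. Among genes with an absolute log2 fold change of at least 1 the majority turned, with 114 higher and 65 lower.

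Of 32 TGF-beta and BMP signalling genes, 13 were called and 12 of them were lower, a different split of directions from that of the other called genes (two-sided Fisher's exact test, adjusted p = 0.042). The authors' deposited table gave −1.45 (SE 0.11) for Id4, −1.50 (SE 0.25) for Id2, −0.94 (SE 0.13) for Smad9 and −0.74 (SE 0.09) for Smad7, all targets or transducers of BMP and TGF-beta receptors. Among 28 collagen genes 18 were called, 14 lower and 4 higher (Fisher's exact test, adjusted p = 0.175), with Col6a1 at −0.56, Col4a5 and Col4a6 at −0.53 and Col8a1 at 1.97 (SE 0.16) in the authors' deposited table. Elastic fibre genes gave 7 lower and 1 higher of 22 (Fisher's exact test, adjusted p = 0.256), led by Mfap5 (−1.34, SE 0.11), Mfap4 (−0.93, SE 0.25) and Mfap2 (−0.78, SE 0.21) in the authors' deposited table. Fibroblast and adventitial markers, which share Mfap5 and 2 collagen genes with those lists, were lower for 9 of 10 called genes (Fisher's exact test, adjusted p = 0.110), among them Sfrp2 (−0.62) and Fap (−0.60) in the authors' deposited table. Proteoglycan and matricellular genes moved both ways, 4 higher and 12 lower (Fisher's exact test, adjusted p = 0.321).

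All 6 called complement genes of 22 were higher in aged WT aorta (Fisher's exact test, adjusted p = 0.042), with C4b at 1.18 (SE 0.10), and C3 and Cfd both at 0.89 in the authors' deposited table. Cfd is also on the adipocyte list, and without it the 5 other genes gave an adjusted p of 0.0583 in Fisher's exact test. All 5 called cytokine and chemokine genes of 43 were higher (Fisher's exact test, adjusted p = 0.0583), including Cx3cl1 (0.59, SE 0.13) and Ccl6 (0.67, SE 0.24) in the authors' deposited table. All 5 called adipocyte genes of 36 were also higher (Fisher's exact test, adjusted p = 0.0583). Immediate early genes, which respond within minutes to stimulation or tissue handling, were lower for 9 of 9 called genes (Fisher's exact test, adjusted p = 0.042), with Jun at −1.02 (SE 0.33) in the authors' deposited table. Among the 21 clock genes 7 were called and all were lower (Fisher's exact test, adjusted p = 0.0638), including Per3 (−0.66, SE 0.13) and Bhlhe41 (−0.58, SE 0.12) in the authors' deposited table. Of 21 calcium exchanger and pump genes 5 were called, 4 lower and 1 higher (Fisher's exact test, adjusted p = 0.555); besides Slc24a4, the authors' deposited table gave −0.45 for the plasma membrane pump Atp2b4, −0.32 for the reticulum pump Atp2a2 and −0.79 for the exchanger Slc8a3. The cell cycle inhibitor Cdkn1a was higher (0.82, SE 0.14) in the authors' deposited table, while the 6 called genes of the senescence list split into 3 higher and 3 lower.

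**Figure D1:**
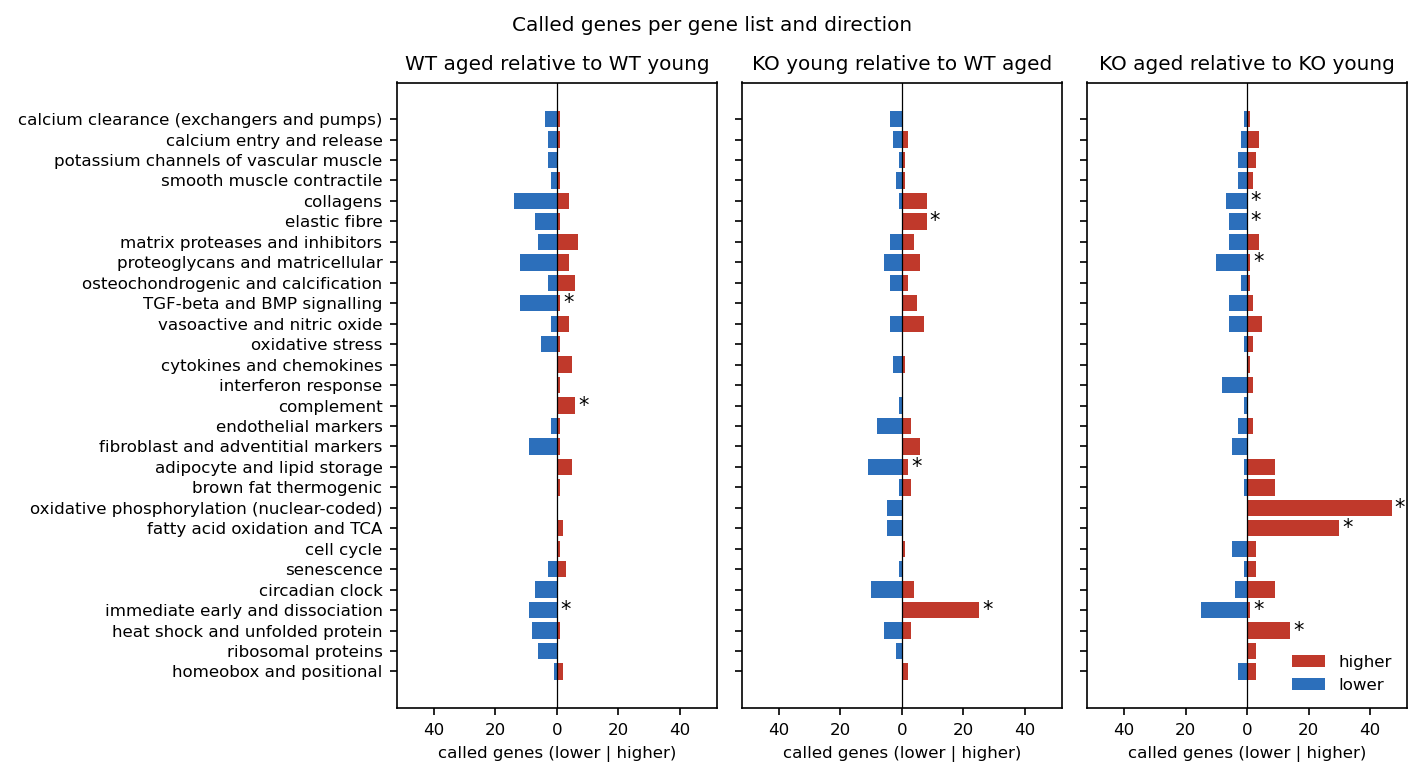
Called genes per fixed gene list, with the number higher drawn to the right in red and the number lower to the left in blue, for the 3 comparisons; a star marks a list with an adjusted p under 0.05 in the Fisher's exact test of direction. The longest bar is that of oxidative phosphorylation in KO ageing, with 47 genes higher and 0 lower.

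The second comparison set KO young against WT aged aorta, so that genotype and age differ together and neither can be assigned a change. Relative to WT aged aorta, KO young aorta had more RNA of every called immediate early and elastic fibre gene. It had less RNA of most called genes of adipocytes and lipid storage. The authors' deposited table, with its sign turned to KO young relative to WT aged, gave the largest increases for the stress and growth factor response genes Atf3 (3.03, SE 0.39), Fos (2.7, SE 0.19), Ccn1 (2.40, SE 0.32) and Fosb (2.37, SE 0.33). The clock genes Npas2 at 2.01 and Bmal1 at 1.91, Nr4a1 at 1.96, Apold1 at 1.87 and Ptgs2 at 1.78 followed in the authors' deposited table. Lowest in KO young in the authors' deposited table were Cntn1 (−2.51, SE 0.46), Col6a5 (−2.47, SE 0.65), the clock repressor gene Ciart (−2.27, SE 0.41), Fkbp5, a glucocorticoid-induced co-chaperone gene (−2.16, SE 0.12), and Snap25 (−2.15, SE 0.44). Ptchd4 (−2.10), Klk10 (−2.09), Pnmt and Slc24a2 (both −2.07) and Nrcam (−1.84) completed the decreases named from the authors' deposited table. The comparison called 1141 of 14661 tested genes, 598 higher and 543 lower in KO young aorta. At an absolute log2 fold change of at least 1 the majority turned here too, with 47 higher and 58 lower.

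All 25 called immediate early genes, of 30 on the list, were higher in KO young aorta (Fisher's exact test, adjusted p = 1.51e-06). The authors' deposited table gave 1.55 (SE 0.10) for Jun, 1.30 (SE 0.09) for Btg2 and 1.15 (SE 0.08) for Dusp1. All 8 called elastic fibre genes were higher (Fisher's exact test, adjusted p = 0.042), with Mfap5 at 0.80 (SE 0.10), the elastic fibre assembly gene Fbln5 at 0.50 (SE 0.08), the crosslinking enzyme gene Lox at 0.42 (SE 0.09) and Mfap4 at 0.41 (SE 0.10) in the authors' deposited table. Fbln5 is also on the list of genes flanking Slc24a4, and the elastic fibre list was not tested without it. Collagens gave 8 higher and 1 lower (Fisher's exact test, adjusted p = 0.0923). All 6 called fibroblast markers, from a list that shares genes with the collagen and elastic fibre lists, were higher (Fisher's exact test, adjusted p = 0.0798). Of 13 called adipocyte and lipid storage genes 11 were lower (Fisher's exact test, adjusted p = 0.042); the authors' deposited table gave −0.98 (SE 0.13) for Thrsp, −0.94 (SE 0.24) for the elongase gene Elovl6 and −0.43 (SE 0.10) for Acly. Clock genes split by arm, with 4 higher and 10 lower (Fisher's exact test, adjusted p = 0.191): Npas2 and Bmal1 stood above, while Bhlhe41 was at −1.03 (SE 0.12), Bhlhe40 at −0.97 (SE 0.12) and Per1 at −0.77 (SE 0.10) in the authors' deposited table.

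Several vascular genes were also lower in KO young than in WT aged aorta. Of 11 called endothelial markers 8 were lower (Fisher's exact test, adjusted p = 0.230), with the connexin genes Gja5 (−0.95, SE 0.22) and Gja4 (−0.78, SE 0.19) and the nitric oxide synthase gene Nos3 (−0.71, SE 0.15) in the authors' deposited table. The 4 called calcium clearance genes were all lower, namely Slc24a2, Atp2b2 (−1.26, SE 0.24), Atp2b1 (−0.40, SE 0.08) and Slc24a3 (−0.21, SE 0.08) in the authors' deposited table; with fewer than 5 called genes this list was not tested. Of the calcium entry and release genes 5 were called (Fisher's exact test, adjusted p = 0.772), among them the ryanodine receptor gene Ryr2 (−0.60, SE 0.09) and Trpc4 (−1.33, SE 0.45) in the authors' deposited table. Alpl, which encodes the tissue-nonspecific alkaline phosphatase that acts in calcification, was higher (1.22, SE 0.19) in the authors' deposited table, and the osteochondrogenic list gave 2 higher and 4 lower (Fisher's exact test, adjusted p = 0.580).

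The third comparison asked which genes changed with age in KO aorta. Aged KO aorta had more RNA of every called gene of oxidative phosphorylation, fatty acid oxidation and heat shock. It had less RNA of most called immediate early, elastic fibre, collagen and proteoglycan genes. The authors' deposited table gave the largest increases for Fkbp5 (2.25, SE 0.08), Zdhhc23 (2.06, SE 0.10), Tsc22d3, a glucocorticoid-induced leucine zipper gene (1.98, SE 0.11), the mitochondrial uncoupling protein gene Ucp3 (1.78, SE 0.18) and Zbtb16 (1.69, SE 0.09). Adamtsl2 at 1.67, the brown fat uncoupling protein gene Ucp1 at 1.62 (SE 0.45), Pnmt at 1.56, Ptchd4 at 1.55 and Apoc1 at 1.54 followed in the authors' deposited table. Among the largest decreases in the authors' deposited table were those of the apelin receptor gene Aplnr (−2.54, SE 0.31), Atf3 (−1.80, SE 0.18), Cstad (−1.58, SE 0.30), Fos (−1.52, SE 0.46) and Cenpf (−1.50, SE 0.31). Rgs1, Wnt2 and then Ptgs2 (−1.39) followed those in the authors' deposited table. Rpl10-ps3, at −2.08 (SE 0.55) in the authors' deposited table, is a pseudogene that can share reads with its parent gene, so its value is uncertain. In total 2083 of 14477 tested genes were called, 1116 higher and 967 lower in aged KO aorta.

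Of 90 nuclear-coded genes of oxidative phosphorylation 47 were called and all 47 were higher in aged KO aorta (Fisher's exact test, adjusted p = 6.72e-12). The authors' deposited table gave 0.50 (SE 0.10) for Cyc1, 0.40 (SE 0.08) for the ATP synthase subunit gene Atp5f1b, 0.57 (SE 0.12) for Uqcrq and 0.49 (SE 0.10) for Uqcrfs1. Fatty acid oxidation and citric acid cycle genes were higher for 30 of 30 called genes of 32 (Fisher's exact test, adjusted p = 2.49e-07), with Acadl at 0.69 (SE 0.11), Eci1 at 0.56 (SE 0.09), Etfdh at 0.54 (SE 0.09) and Sucla2 at 0.54 (SE 0.09) in the authors' deposited table. Beside these, 9 of 10 called brown fat genes were higher (Fisher's exact test, adjusted p = 0.0638), including Ppargc1a, a coactivator of mitochondrial biogenesis (0.89, SE 0.14), and Kcnk3 (0.87, SE 0.16), while Prdm16 was lower (−0.33, SE 0.08) in the authors' deposited table. Adipocyte and lipid storage genes were higher for 9 of 10 called genes (Fisher's exact test, adjusted p = 0.0638). The same oxidative phosphorylation list had 0 called genes in WT ageing, and 5 called genes, all lower in KO young, against WT aged aorta (Fisher's exact test, adjusted p = 0.0638); whether the ageing effect on this list differed between genotypes was not tested, since the difference test needs genes called in both. None of the 15 mitochondrially coded genes was called in any comparison.

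All 14 called heat shock and unfolded protein genes were higher in aged KO aorta (Fisher's exact test, adjusted p = 0.00193), with Hspd1 at 0.47 (SE 0.09), Hspb1 at 0.43 (SE 0.10), Hspb7 at 0.38 (SE 0.06) and Herpud1 at 0.35 (SE 0.07) in the authors' deposited table. Immediate early genes were lower for 15 of 16 called genes (Fisher's exact test, adjusted p = 0.00178), including Egr3 (−1.32, SE 0.15), Egr2 (−1.38, SE 0.21) and Jun (−1.02, SE 0.10) in the authors' deposited table.  All 6 called elastic fibre genes were lower (Fisher's exact test, adjusted p = 0.042), with Fbln5 at −0.35 (SE 0.09), Fbn1 at −0.32 (SE 0.09) and the elastin gene Eln at −0.30 (SE 0.08) in the authors' deposited table. Here too the list was not tested without Fbln5, which flanks Slc24a4, though both groups of this comparison are labelled KO. All 7 called collagens were lower (Fisher's exact test, adjusted p = 0.0361), as were 10 of 11 called proteoglycan and matricellular genes (Fisher's exact test, adjusted p = 0.0359), among them Col3a1 (−0.31, SE 0.10), Comp (−0.80, SE 0.11) and Smoc1 (−0.54, SE 0.07) in the authors' deposited table. All 5 called fibroblast and adventitial markers were lower as well (Fisher's exact test, adjusted p = 0.0638). That list shares 2 genes with the collagen list, 2 with the proteoglycan list and 1 with the elastic fibre list, so it is not separate evidence.

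Other lists moved in both directions in KO ageing. Clock genes gave 9 higher and 4 lower (Fisher's exact test, adjusted p = 0.418): Ciart, Per1 (0.87, SE 0.09) and Per2 (0.74, SE 0.09) were higher and Npas2 (−0.97, SE 0.12) was lower in the authors' deposited table. Interferon response genes were lower for 8 of 10 called genes (Fisher's exact test, adjusted p = 0.110), with Iigp1 at −0.74 (SE 0.19) and Gbp9 at −0.67 (SE 0.24) in the authors' deposited table. The proliferation genes Mki67 (−1.24, SE 0.21) and Top2a (−1.26, SE 0.25) were lower in the authors' deposited table, and the cell cycle list gave 3 higher and 5 lower (Fisher's exact test, adjusted p = 0.634). Among vasoactive genes 5 were higher and 6 lower (Fisher's exact test, adjusted p = 0.840), with the adrenoceptor gene Adra1d at −0.71 (SE 0.11), the guanylate cyclase gene Gucy1a1 at −0.38 (SE 0.06) and Nos3 at 0.50 (SE 0.13) in the authors' deposited table. Smooth muscle contractile genes were called for 5 of 25, 2 higher and 3 lower (Fisher's exact test, adjusted p = 0.772); Myocd, a master regulator of that programme, was at 0.58 (SE 0.09) in the authors' deposited table.

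Further lists held few calls or moved both ways. In WT ageing, heat shock genes were lower for 8 of 9 called genes (Fisher's exact test, adjusted p = 0.170). All 6 called ribosomal protein genes were lower there (Fisher's exact test, adjusted p = 0.0918). Genes of oxidative stress gave 1 higher and 5 lower in WT ageing (Fisher's exact test, adjusted p = 0.366). Matrix protease and inhibitor genes gave 7 higher and 6 lower in WT ageing (Fisher's exact test, adjusted p = 0.706), and Adamts8 stood at 1.13 (SE 0.11) in the authors' deposited table. Of 36 macrophage and myeloid markers 4 were called in WT ageing, 3 in KO young against WT aged and 2 in KO ageing, too few for a test. Potassium channel genes gave 3 higher and 3 lower in KO ageing, as did homeobox genes. No neutrophil, B cell, erythroid or MHC class II gene on the lists was called in any comparison.

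**Figure D2:**
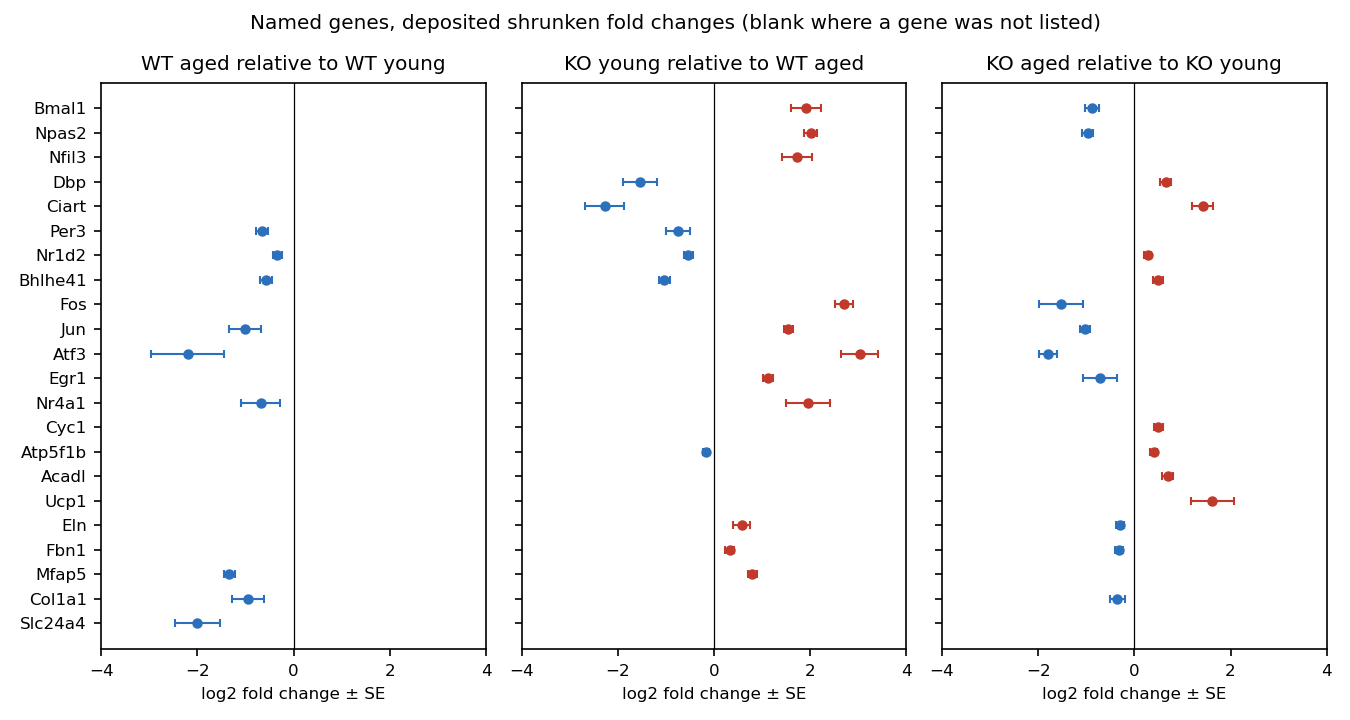
Log2 fold changes with their SE for genes of the clock, immediate early, respiratory, brown fat and matrix lists and for Slc24a4, from the authors' deposited tables, in the 3 comparisons. The genes were chosen after their values were seen. Points right of 0 are higher in the group named first, and a blank marks a gene not listed; Fos stands at 2.7 in KO young relative to WT aged and at −1.52 in KO aged relative to KO young.

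The 2 ageing comparisons share no library, so their overlap can be compared with that of independent lists. They had 438 genes in common, of which 148 were higher with age in both genotypes, 213 lower in both and 77 in opposite directions. Independent lists of these lengths would share 58.7 genes higher in both, 65.4 lower in both and 126 opposite, taking 14374 genes as tested in both. Direction in one genotype was associated with direction in the other (two-sided Fisher's exact test, p = 2.52e-43, over genes, which are not independent). Among genes higher in both, the authors' deposited tables gave Ptchd4 at 2.14 in WT and 1.55 in KO, Cntn1 at 3.52 and 1.28, Sphkap at 2.60 and 1.25, Fkbp5 at 1.06 and 2.25, Arrdc2 at 0.94 and 1.13, and the non-muscle myosin gene Myh14 at 1.96 and 0.89. Among genes lower in both, examples in the authors' deposited tables were Atf3 at −2.20 in WT and −1.80 in KO, Nipal4 at −1.34 and −1.23, Jun at −1.02 in each, the DNA demethylase gene Tet1 at −1.07 and −0.93, and Igsf9 at −1.21 and −0.87.

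Of those 438 genes, 131 had ageing effects that differed between genotypes at an adjusted p under 0.05 in a test of the difference of the 2 fold changes. The effect was more positive in KO for 78 and more positive in WT for 53 genes, and 76 of the 131 changed in opposite directions. Genes called in both tables with opposite signs pass such a test almost by selection, as 76 of 77 did here, so that share says nothing further. The differences, KO minus WT, were largest upwards for Noct, a clock-controlled deadenylase-family gene (1.38, SE 0.29), Kctd16 (1.20, SE 0.18), Fkbp5 (1.19, SE 0.40), Fmo1 (1.08, SE 0.18), Bhlhe41 (1.07, SE 0.16) and Mme, which encodes neprilysin (1.02, SE 0.20); Acss1 and Cys1 tied with Mme at 1.02. Downwards they were largest for Cntn1 (−2.24, SE 0.61), Spon2 (−2.06, SE 0.76), the microRNA gene Mir143 (−1.95, SE 0.46) and the interferon lambda receptor gene Ifnlr1 (−1.80, SE 0.31), and for the pseudogene Rpl10-ps3 (−3.40, SE 0.72) and the retrotransposed ribosomal gene Rps27rt (−2.37, SE 0.60), which can share reads with their parent genes and are uncertain. The values of Fkbp5, Acss1, Cntn1, Spon2 and Mir143 were shrunken below 0.7 of the z implied by their p-value in at least 1 of the tables. The test covers only genes called in both tables: 1290 genes called in WT ageing and 1645 called in KO ageing were not called in the other, and whether those differ was not tested.

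**Figure D3:**
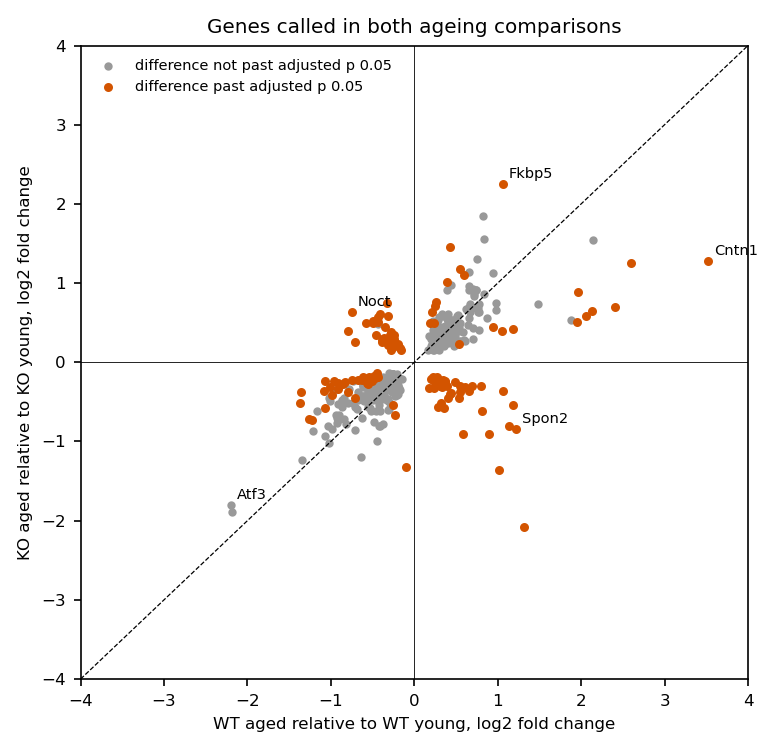
Log2 fold change with age in WT (x axis) and in KO aorta (y axis) for the 438 genes called in both ageing comparisons, from the authors' deposited tables; orange points are the 131 genes whose difference passed an adjusted p of 0.05, and the dashed line marks equal change. Most points lie in the quadrants of equal direction, and 77 lie in the other quadrants.

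The KO young against WT aged comparison shares its WT aged libraries with WT ageing and its KO young libraries with KO ageing, which alone raises the overlap. With WT ageing it had 398 genes in common; 154 were higher and 211 lower in WT aged than in both young groups, and 33 went the other way. Unchanged groups sharing these libraries gave 4.98 genes of the same direction in simulation, and independent lists would give 28.6 and 40.4. With KO ageing it had 656 genes in common, 305 lower and 348 higher in KO young than in both aged groups and 3 otherwise, against 5.96 simulated and 41.9 and 39.9 for independent lists. A gene changed in the shared group alone would be called in both comparisons with the same direction, and neither reference value covers this. Part of each excess may therefore come from the shared libraries, which could not be split here. Summing the deposited fold changes of WT ageing and of KO young against WT aged gives a value, without a test, for KO young relative to WT young. Of the 398 genes, 18 summed to at least 1 and 10 to −1 or less; Spp1 summed to 1.74, Nfasc to 2.19, Tnni3k to 1.70, and Bhlhe41 to −1.61. Rimklb summed to −1.77 and Ccn1 to 2.30, but each has 1 value shrunken far below what its p-value implies. These were 0.09 (SE 0.17) for Rimklb in KO young against WT aged and −0.10 (SE 0.20) for Ccn1 in WT ageing, in the authors' deposited tables.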

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

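The tests of the explanations below were all chosen after the results were seen. Values per library were not analysed here, so single libraries were not examined and other splits of the libraries were not counted.

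The ageing effects of 12 named genes differed between genotypes in the test of the difference. Higher in KO than in WT were the differences of Noct (1.38), Kctd16 (1.20), Fkbp5 (1.19), Fmo1 (1.08), Bhlhe41 (1.07) and Mme (1.02). Lower were those of Cntn1 (−2.24), Spon2 (−2.06), Mir143 (−1.95), Ifnlr1 (−1.80), Rpl10-ps3 (−3.40) and Rps27rt (−2.37). Among the 12 genes, all but Fkbp5 and Cntn1 were called with opposite directions in WT and KO ageing. Such genes pass this test almost by selection, so passing it adds little for them. Fkbp5 rose with age by 1.06 in WT and 2.25 in KO, and Cntn1 by 3.52 and 1.28, in the authors' deposited tables. Both genes rest on a strongly shrunken value, so the sizes of their differences are uncertain.

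Clock genes differed between KO young and both aged groups. An age effect common to both genotypes was argued against by 4 of the 5 clock genes called in both ageing comparisons, which changed in opposite directions. Collection at another time of day may contribute: in KO young against WT aged all 14 called clock genes lay on the side of their arm of the clock (two-sided Fisher's exact test of arm against direction, p = 0.000999, over genes, which are not independent), as did 12 of 13 in KO ageing, which shares the KO young libraries. A shift of the clock that depends on genotype and age would give the same, and the labels used here give no time of day. An effect of genotype stays open, as untested: by sums of 2 deposited fold changes, KO young relative to WT young lay from −1.61 to −0.87 over 4 clock genes, all below 0, and KO aged relative to WT aged from −0.89 to 1.04 over 11, with 4 above 0 and 7 below.

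Of 16 immediate early genes called in KO ageing, 15 were higher in KO young than in KO aged and 1 was lower. All 25 called in KO young against WT aged were higher in KO young. Uneven handling of single pools in KO young or WT aged may contribute and cannot be told apart from a change of whole groups: the 25 called genes had a median SE of 0.141 in that comparison, and random called genes matched on mean and size of change had a median of 0.143, between 0.113 and 0.205 at the 5th and 95th percentiles. Matched on the mean alone, the 95th percentile was 0.111, so the outcome depends on the matching, and values per library were not analysed here. The smallest pool matched on mean and size of change held 11 genes. Called genes of this list had a larger median SE in the ageing comparisons, 0.376 over 9 genes in WT ageing and 0.184 over 16 in KO ageing. Whether this comes from uneven pools of WT young or KO aged was not tested. Effects of age and of genotype stay open, as untested. By sums of 2 deposited fold changes, KO young relative to WT young lay from 0.07 to 1.28 over 9 immediate early genes, all above 0 with a median of 0.68, and KO aged relative to WT aged from −0.64 to 1.23 over 15, with a median of 0.52, 11 above 0 and 4 below. Some values in these sums were shrunken far below what their p-value implies, such as Dusp1 in WT ageing (−0.47, SE 0.60). A decrease shrunken too far in an ageing comparison leaves the sum too high, so the share above 0 is uncertain.

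All called nuclear-coded oxidative phosphorylation genes (47 of 90) and fatty acid oxidation genes (30 of 32) were higher in KO aged than in KO young aorta. More brown fat in the KO aged pools could bring such transcripts with it: 9 of 10 called brown fat genes were higher there, and the direction test of that list gave an adjusted p of 0.0638. Brown fat and a change of the aorta itself cannot be told apart, since values per library were not analysed here. Without the 2 genes and the 1 gene shared with the brown fat list, 45 oxidative phosphorylation genes were higher and 0 lower (two-sided Fisher's exact test, unadjusted p = 4.50e-13), and 29 fatty acid oxidation genes were higher and 0 lower (Fisher's exact test, unadjusted p = 1.78e-08). The whole lists gave an unadjusted p of 1.22e-13 and 9.05e-09 in Fisher's exact test. With so few genes left out the outcome was nearly fixed, so it does not bear on brown fat.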

How the results depend on the processing

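The alternatives with light shrinkage, without brown fat genes and without the adipocyte gene of the complement list were chosen after seeing the data. A mean normalized count of at least 50 kept each count within 1.5 times, as did named symbols only for the 3 counts of called genes, the counts it was run on. At an adjusted p under 0.01 the called genes numbered 1050 in WT ageing, 700 in KO young against WT aged and 1221 in KO ageing, and at an absolute log2 fold change of at least 1 they numbered 179, 105 and 99. The latter turned the majority in WT ageing to 114 higher and 65 lower, and in KO young against WT aged to 47 higher and 58 lower; the cause was not tested. Lists past the direction test numbered 7 and 3 under these settings. At 0.01, adjusted p was 0.0629 for collagens in KO ageing, 0.0607 for elastic fibre genes in KO young, and 0.0947 for TGF-beta and BMP genes and 0.176 for immediate early genes in WT ageing; fewer called genes entered. Without the shared adipocyte gene it was 0.0583 for complement genes in WT ageing, with 1 gene fewer. Genes of one direction shared by both ageing comparisons numbered 169 and 8, by WT ageing and KO young against WT aged 213 and 25, and by KO ageing and KO young against WT aged 368 and 30. Genes with a genotype difference numbered 55 and 5, and 115 with light shrinkage. No list that could be tested again changed its direction. Complement genes in WT ageing and elastic fibre genes in KO ageing had too few calls for a test at 0.01, and at a log2 fold change of 1 only immediate early genes could be tested again among the lists that passed, in KO young against WT aged and in KO ageing. No paired analysis was possible because the deposited comparison tables carry no values per library; for that reason leaving out replicates, another tool and another normalization were not run. Depth is unknown and sets no limit that could be given.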

Other observations

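The list of glucocorticoid-responsive genes in this part was written after the tables were seen, and the genes named here were chosen after their values were seen. Of its 25 genes, 21 were called in KO ageing, 18 of them higher (two-sided Fisher's exact test, p = 0.00327), and 18 were called in KO young against WT aged, 15 of them lower in KO young (Fisher's exact test, p = 0.00308). In WT ageing 5 were higher and 2 lower (Fisher's exact test, p = 0.251). In KO ageing the authors' deposited table gave 1.25 for Cebpd, 1.18 for Klf15, 1.02 for Nfkbia and 0.86 for Sgk1. Because the list was drawn from genes seen to change, these p-values are not independent evidence.

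A contrast of KO aged with WT aged aorta was added later and was not planned. By the difference of 2 deposited fold changes, with no test, KO aged relative to WT aged aorta gave 8 genes at 1 or more and 3 at −1 or less of 656. Actn2 stood at 1.53, Atf3 at 1.23 and Fos at 1.18, and Aplnr at −1.22 and Cntn1 at −1.23. Uneven shrinkage makes such sizes uncertain. Cntn1 rests on 1.28 (SE 0.55) in KO ageing and −2.51 (SE 0.46) in KO young against WT aged, and Fos on −1.52 (SE 0.46) and 2.7 (SE 0.19), in the authors' deposited tables.

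Of the 16 genes flanking Slc24a4 on the list fixed before the data were examined, 0 were called in WT ageing, 2 in KO young against WT aged and 3 in KO ageing. A wider window was chosen after the tables were seen. Among the 40 protein-coding genes nearest to Slc24a4 in the GRCm38 gene order, 3 were called in WT ageing, 5 in KO young against WT aged and 9 in KO ageing, against 7.87%, 5.22% and 9.44% of all other named protein-coding genes (one-sided Fisher's exact test, p = 0.620, 0.0563 and 0.0110, unadjusted). The background includes genes that were not tested, so these p-values are rough. Fbln5, Ccdc88c and Rps6ka5 were among them in both comparisons with KO young.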
